A study of Mus musculus with 26 samples.

How the data were processed

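RNA was measured by sequencing in 26 mouse libraries of blood progenitors sorted by flow cytometry, made from low-input SMARTer cDNA. The deposited series table gives, for 22958 genes with RefSeq accessions, RPKM values (reads scaled to transcript length and to library size) that the authors calculated, and beside them the deposited raw read counts of each library. The submitters' processing notes name Bowtie 0.12.7 and the mm9 build. The counting tool, its filters and the strand are not stated, and no coordinates are used here.

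The counts were tested against the RPKM values before use, because a second header line pushes each count 1 line below its gene. With that offset of 1 line, 99.92% of gene and library pairs were at zero in both units or in neither, against 59.41% without it. Over 19157 genes with a single transcript, 98.83% of the ratios of count to RPKM lay within 1% of the product of a factor per gene and a factor per library. All sample columns were matched to the labels. Of the 22958 accessions, 22535 were found in the reference gene table, and 794 entries share a symbol with another. The symbols of the deposited table are used in the text.

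Total counts ran from 149882 to 9508328 per library with a median of 3514280.5, and the second lowest was 977021. Counting intervals (exact, at 95%) and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. A fold against a group in which every library was at 0 is given as a lower bound, taken against a floor of 3 counts over the group. With 1 to 3 counts in the lower group, the ratio of counts scaled to depth is given with its interval. The fitted fold changes of such genes depend on the prior count of 0.125 and are not given.

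The test planned before the data were examined was limma-trend on log2 of RPKM plus 1, on the understanding that the table held RPKM alone. Because it also holds raw counts, the main test became the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, and the limma test was kept as an alternative. Genes at 1 RPKM or more in at least 2 libraries were kept, which left 13136 genes. One model of the 10 group means was fitted to all 26 libraries after TMM scaling, with no term for the replicate number. Its common dispersion was 0.385 and its prior degrees of freedom were 6.02. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, two-sided, and a gene is called at an adjusted p under 0.05. The p-values measure the spread between these libraries, since the labels do not say whether libraries of a group came from separate animals or pools.

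There were 10 comparisons between groups and 2 differences between such comparisons (interactions). The comparisons, the filter, the 21 gene lists and the rule for the genes named were fixed before the data were examined. The rule takes the genes of the sort gates, up to 4 called members of each list with the largest change (or the 2 members of highest mean where none was called), and the 10 called genes with the largest rise and fall among those at 5 RPKM or more in the higher group whose libraries did not overlap between groups. It takes 5 per direction for the interactions. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation, with adjustment over the lists within a comparison. Fry, which tests whether a list moves one way on balance, was run beside them. The lists are early lymphoid, B lineage, T lineage, granulocyte-monocyte, macrophage, mast cell and basophil, erythroid, embryonic globin, megakaryocyte, stem cell, endothelial, hepatoblast and endoderm, mesenchyme, fetal programme, MHC class II and presentation, interferon response, proliferation, immediate early and stress, heme and iron, cytokine receptors, and ribosomal protein genes. Some genes stand in more than 1 list. Signatures of the adult steps are the 100 genes of largest rise among those called (all 48 called for CLP against LMPP), without the sort genes, and were tested in the fetal comparisons, which share no library with them. Similarity is the Spearman correlation across genes between a fetal library and the mean of an adult group, and genes are not independent replicates.

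In the yolk sac only the replicate number 1 clearly pairs its libraries. The deviations of positive and negative libraries of the same number from their group means correlated at 0.777, 0.407 and 0.331, all above the minimum of 0.1 set for pairing. Numbers 2 and 3 were not told apart, since positive library 3 correlated at 0.413 with negative library 2. Deviations from a group mean cancel out, so a distinct pair numbered 1 moves the other libraries together. Any pairing is read from the data, since the labels do not say what a number marks. The replicate block is given where it changes a yolk sac call. Outside the yolk sac only FL E10.5 numbers 1 and 2 met that minimum.

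The tools were tested on simulated counts with the depths and dispersions of the libraries, in which 100 of 12783 genes were changed by a log2 of 2 and 100 by a log2 of 4. In the yolk sac design edgeR recovered 37% and 83% of them with 6.25% false calls, against 40.09% false calls for limma and 16.37% for DESeq2. In the fetal liver E11.5 design edgeR recovered 47% and 86% with 2.206% false calls, against 8.333% and 16.39%. In the adult LMPP and HSC design edgeR recovered 28% and 65% with 2.105% false calls, against 45.55% and 19.08%. The counts were drawn in a single run from the dispersions that edgeR estimated, without shared differences between libraries. These shares therefore do not rank the tools on the real data.

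The alternatives set beforehand were no filter, a filter at 5 RPKM, a fit with the replicate block, limma with a pseudocount of 0.1, limma after quantile normalization, a fit of the compared groups alone, other signature sizes (50 and 200 genes), the 1000 most variable genes for similarity, and leaving out each library in turn. Where that left an adult group with 1 library, the lone library is assumed to vary like the other groups. DESeq2 1.42.0, the size factors of DESeq2 within edgeR, and leaving out both yolk sac libraries numbered 1 were added after the data were seen, and limma on log2 of RPKM plus 1, the test planned at first, became an alternative then. Some alternatives set beforehand for the counts of genes were extended after the data were seen. For the lists these are no filter and leaving out libraries, for the signatures no filter, for the similarity leaving out libraries, and for the genes shared by stages all but the pseudocount of 0.1, quantile normalization and a minimum log2 of 1. No library was left out of the main results. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.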

Results

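RNA sequencing was reported for 26 libraries of C57BL/6 mouse blood progenitors in 10 groups. There were 18 fetal libraries in 6 groups of 3. The lineage-negative Kit+ cells of the yolk sac at embryonic day 9.5 (YS E9.5) and of the fetal liver at day 10.5 (FL E10.5) came from Rag1-GFP reporter mice and were sorted into cells positive or negative for both the reporter and the interleukin 7 receptor (IL7R). The fetal liver cells of day 11.5 (FL E11.5) came from wild-type mice and were sorted as positive or negative for both Flt3 and IL7R. The 8 adult libraries were from bone marrow, with 2 each of haematopoietic stem cells (HSC), lymphoid-primed multipotent progenitors (LMPP), common lymphoid progenitors (CLP) and pro-B cells, numbered 2 and 3.

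Total counts were 3326304 to 7658934 per library in YS E9.5 negative cells and 2200456 to 9508328 in positive cells. They were 2469580 to 3431433 in FL E10.5 negative and 3597128 to 6255327 in FL E10.5 positive cells. In FL E11.5 they were 149882 to 5451434 in negative and 2105821 to 3866019 in positive cells. Adult totals were 2386813 to 2568271 in HSC, 2783976 to 3642860 in LMPP, 977021 to 3603758 in CLP and 3993415 to 4140093 in pro-B cells. Levels are RPKM as mean ± SD, with n = 3 in fetal and n = 2 in adult groups, and fold changes are log2 with their standard error (SE). In each gene named as called, every library of one group lay above every library of the other unless the text says otherwise.

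The yolk sac comparison asked what sets the double-positive cells of day 9.5, before definitive stem cells are described, apart from double-negative cells of the same tissue and day. The positive cells carried early lymphoid transcripts and less of the megakaryocyte transcripts. Lsp1, an actin-binding protein of leukocytes, stood at 1104 ± 485 RPKM against 61.6 ± 2.54 (log2 4.12, SE 0.35, adjusted p = 6.77e-07). Rag2, a subunit of the recombinase that assembles antigen receptor genes, was at 5.77 ± 2.87 RPKM with 1 count in the negative libraries together (ratio 249, interval 44.2 to 9860, adjusted p = 0.000911). Cd7, a surface protein of early T and natural killer lineage cells, was at 11.6 ± 6.45 RPKM and at 0 in every negative library, at least 50-fold higher (adjusted p = 0.00407).

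Of the genes tested, 63 were called in the yolk sac, 59 higher and 4 lower in positive cells (132 and 24 with DESeq2, 75 and 13 with the replicate block). The gate genes followed the labels. Il7r was at 65.2 ± 32.3 RPKM against 0.256 ± 0.311 (adjusted p = 0.000742), and Flt3, which was not part of this gate, at 9.92 ± 9.48 against 0.0855 ± 0.148 (log2 6.70, SE 1.01, adjusted p = 0.00118). Rag1 itself was low, at 0.286 ± 0.0562 RPKM against 0.00936 ± 0.0162 (ratio 34.3, interval 5.73 to 1396), and missed the threshold (adjusted p = 0.0767). Bcl11a, a transcription factor of lymphoid development, was at 63.7 ± 29.95 RPKM against 14.8 ± 5.04 (log2 2.42, SE 0.33, adjusted p = 0.000655). The purinergic receptor gene P2ry12 was at least 308-fold higher (30.5 ± 15.4 RPKM, adjusted p = 0.00300). Gimap7, a GTPase of lymphocytes, was at least 41.8-fold higher (7.94 ± 3.87 RPKM, adjusted p = 0.00317). Rorc, the nuclear receptor gene of innate lymphoid cells and thymocytes, was at 15.0 ± 12.8 RPKM (ratio 518, interval 92.4 to 20480, adjusted p = 0.00397). Stc1, a secreted glycoprotein, had a ratio of 618 (interval 111 to 24460, adjusted p = 0.000682). Of the 4 lower genes, Gata2, a transcription factor of stem and progenitor cells, was at 5.17 ± 0.613 RPKM against 27.9 ± 12.8 (log2 -2.40, SE 0.45, adjusted p = 0.0103). Its adjusted p was 0.0840 without negative library 3 and 0.0690 without positive library 3.

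By list, 4 of 19 tested early lymphoid genes were called higher in the yolk sac positive cells (9 adjusted over the list alone), and 15 lay above 0 (adjusted p = 1.65e-16 for the list). In the T lineage list 1 of 9 was called higher (3 adjusted over the list alone, adjusted p = 4.89e-07). In the list of MHC class II and presentation genes 1 of 12 was called higher and 10 lay above 0 (adjusted p = 3.89e-07). The megakaryocyte list was lower as a whole, with 1 of 16 genes called lower and 1 above 0 (adjusted p = 2.02e-10). These 4 calls held with an estimated correlation (adjusted p = 0.000269, 0.000540, 0.0252 and 0.00134). The interferon list was called higher, with 18 of 20 genes above 0 (adjusted p = 1.16e-05, and adjusted p = 0.138 with an estimated correlation). The B lineage list had no called member and a list adjusted p of 0.0194, with adjusted p = 0.22 with an estimated correlation. It was 0.0554 with the replicate block, 0.0705 without negative library 1 and 0.198 without positive library 3.

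The lists of other mature lineages gave weaker results in the yolk sac. The erythroid list had 2 of 20 genes above 0 and none called (adjusted p = 0.000297, and adjusted p = 0.262 with an estimated correlation), and its adjusted p was 0.250 without negative library 3 and 0.0717 without positive library 1. The heme and iron list lay lower with no called gene (adjusted p = 0.00576, and adjusted p = 0.22 with an estimated correlation), with 0.102 without positive library 2. The granulocyte-monocyte list had 6 of 20 genes above 0 (adjusted p = 0.0167, and adjusted p = 0.22 with an estimated correlation), with 0.174 without negative library 2 and 0.704 without positive library 1. The endothelial list lay higher with no called gene (adjusted p = 0.0169, and adjusted p = 0.138 with an estimated correlation), with 0.0521 without negative library 1, 0.0555 without negative library 3 and 0.247 without positive library 1. The stem cell list (5 of 19 genes higher and 1 lower when adjusted over the list alone) was not called (adjusted p = 0.131). Nor were the lists of macrophage (0.231), mast cell and basophil (0.400), embryonic globin (0.117), hepatoblast and endoderm (0.266), mesenchyme (0.649), fetal programme (0.387), proliferation (0.790), immediate early and stress (0.781), cytokine receptor (0.790) and ribosomal protein genes (0.781).

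Endoderm transcripts stood high in both yolk sac libraries numbered 1, with Afp at 4319 RPKM in the negative and 5404 in the positive library and a mean of 39.87 in the other 4. Without both libraries 60 genes were called, 46 of them among the 63. The count was 35 and 27 without negative libraries 2 and 3, and 41 and 32 without positive libraries 2 and 3. A fit of the yolk sac libraries alone called 2 genes, Lsp1 among them. Notch1, a receptor that directs T lineage fate, was called higher (log2 2.15, SE 0.46, adjusted p = 0.0280), but its adjusted p was 0.0621 with the replicate block and 0.0599 to 0.199 without any of the 3 negative libraries or positive library 3.

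The fetal liver comparison at day 10.5 put the same question to the reporter-positive cells of the liver. Early lymphoid transcripts stood out, with a few called genes of the granulocyte-monocyte list. The camera call of that list was lost with an estimated correlation (adjusted p = 0.1205). Lsp1 was at 789 ± 186 RPKM against 27.1 ± 16.3 (log2 4.76, SE 0.36, adjusted p = 8.54e-08). Notch1 was at 12.1 ± 3.42 RPKM against 0.705 ± 0.403 (log2 4.01, SE 0.51, adjusted p = 0.000159). Ptprc, the pan-leukocyte antigen CD45, was at 91.4 ± 1.53 RPKM against 18.6 ± 7.17 (log2 2.18, SE 0.37, adjusted p = 0.00337). Ifitm3, an interferon-inducible membrane protein gene, was at 208 ± 56.7 RPKM against 23.4 ± 10.5 (log2 3.08, SE 0.51, adjusted p = 0.00272).

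At FL E10.5 114 genes were called, 110 higher and 4 lower in positive cells (122 and 19 after quantile normalization, 254 and 27 with DESeq2, 288 and 80 in a fit of both groups alone). Il7r was at 52.2 ± 8.06 RPKM against 0.347 ± 0.495 (adjusted p = 0.00158). Rag1 was at 0.768 ± 0.139 RPKM with a ratio of 13.7 (interval 4.49 to 68.1) and missed the threshold (adjusted p = 0.0626). Flt3 was at 23.6 ± 2.35 RPKM against 1.14 ± 0.748 (log2 4.31, SE 0.81, adjusted p = 0.00831, and 0.0756 without negative library 1). Efna5, a ligand of Eph receptors, was at 8.49 ± 0.514 RPKM and at 0 in the negative cells, at least 120.0-fold higher (adjusted p = 0.00170). Stc1 had a ratio of 624 (interval 112 to 24650, adjusted p = 0.000491). Cd7 was at least 26.6-fold higher (9.40 ± 0.409 RPKM, adjusted p = 0.00913), with an adjusted p of 0.0596 without negative library 1 and 0.0647 without negative library 2. Itgam, an integrin chain of myeloid cells, was at 12.1 ± 2.49 RPKM against 1.14 ± 0.104 (log2 3.29, SE 0.62, adjusted p = 0.00870), with an adjusted p of 0.0668, 0.0862 and 0.0506 without negative libraries 1, 2 and 3. The 4 lower genes were Nr3c1, Pgm1, Tmem14c and Sdhd, with log2 changes of -1.90, -1.67, -0.98 and -0.70. Each lost its call whichever of the 6 libraries was left out, with adjusted p-values of 0.0880 to 0.139, 0.0533 to 0.304, 0.0729 to 0.216 and 0.0596 to 0.0863.

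By list, all 19 early lymphoid genes lay above 0 at FL E10.5, 6 called higher (11 adjusted over the list alone, adjusted p = 2.35e-22 for the list). Dntt, Blnk and Ly6d count among the 19 but rested mainly on positive library 3, with Blnk at 19.06 RPKM and Ly6d at 9.11. In both other positive libraries the 3 genes lay under 1% of their adult CLP level. The T lineage list had 1 gene called higher (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.000173). The endothelial list had none called (4 adjusted over the list alone) and 11 of 16 above 0 (adjusted p = 0.00102). These calls held with an estimated correlation (adjusted p = 4.34e-05, 0.00950 and 0.0417). The granulocyte-monocyte list had 3 of 20 genes called higher and 13 above 0 (adjusted p = 0.00489, and adjusted p = 0.121 with an estimated correlation). The macrophage list had none called and 9 of 11 above 0 (adjusted p = 0.00164, and adjusted p = 0.0758 with an estimated correlation). All 12 genes of MHC class II and presentation lay above 0 (adjusted p = 1.34e-05, and adjusted p = 0.0588 with an estimated correlation), as did 18 of 20 interferon genes (adjusted p = 0.000222, and adjusted p = 0.121 with an estimated correlation). The stem cell list had 2 of 19 called higher (adjusted p = 0.00958, and adjusted p = 0.0773 with an estimated correlation).

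The erythroid list lay lower at FL E10.5, with 1 of 20 genes above 0 and none called (adjusted p = 3.87e-06, and adjusted p = 0.119 with an estimated correlation). The megakaryocyte list had 5 of 16 above 0 (adjusted p = 0.000943, and adjusted p = 0.0588 with an estimated correlation), and the heme and iron list 2 of 14 (adjusted p = 0.000251, and adjusted p = 0.0773 with an estimated correlation). The immediate early and stress list lay higher (adjusted p = 0.00344, and adjusted p = 0.119 with an estimated correlation), with 0.0573 without positive library 3. The fetal programme list (adjusted p = 0.0434, and adjusted p = 0.222 with an estimated correlation) had 0.113, 0.0516 and 0.169 without negative library 2, negative library 3 and positive library 1. The cytokine receptor list (adjusted p = 0.0151, and adjusted p = 0.121 with an estimated correlation) had 0.0978 without negative library 2 and 0.0790 without positive library 3. The ribosomal protein list lay lower (adjusted p = 0.00285, and adjusted p = 0.305 with an estimated correlation), with 0.160 without positive library 1. The lists of B lineage (0.883), mast cell and basophil (0.113), embryonic globin (0.852), hepatoblast and endoderm (0.830), mesenchyme (0.830) and proliferation genes (0.0611) were not called. In positive library 3 Dntt, the template-free DNA polymerase of lymphocytes, was at 250.6 RPKM and at 0 in the other positive libraries. The count of 114 was 41, 33 and 64 without negative libraries 1, 2 and 3, and 67, 65 and 70 without positive libraries 1, 2 and 3.

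The day 11.5 comparison used Flt3 in place of the reporter. The positive cells held lymphoid transcripts and the negative cells erythroid and megakaryocyte transcripts. Notch1 was at 14.4 ± 1.57 RPKM against 0.578 ± 0.128 (log2 4.82, SE 0.57, adjusted p = 3.43e-05). Rag2 was at 38.8 ± 18.5 RPKM against 2.98 ± 2.70 (log2 4.54, SE 0.80, adjusted p = 0.00329), and Cd7 at 39.4 ± 7.66 against 0.382 ± 0.662 (log2 6.26, SE 1.15, adjusted p = 0.00884). Gata1, the transcription factor of the erythroid and megakaryocyte lineages, was at 1.36 ± 1.71 RPKM in positive and 224 ± 36.1 in negative cells (log2 -7.37, SE 1.32, adjusted p = 0.00342). Gp1ba, a platelet receptor gene, was at 0 in positive and 8.56 ± 2.17 RPKM in negative cells, at least 62.4-fold lower (adjusted p = 0.00703).

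At FL E11.5 229 genes were called, 150 higher and 79 lower in positive cells. The split was 82 and 89 without negative library 3, 60 and 51 without negative library 2 and 107 and 21 without positive library 3, and 290 and 246 with DESeq2. Il7r was at 80.3 ± 12.3 RPKM against 0.459 ± 0.795 (adjusted p = 0.00151) and Flt3 at 47 ± 13.1 against 0.930 ± 0.913 (adjusted p = 0.000761). Rag1, which was outside this gate, was at 2.28 ± 1.89 RPKM and at 0 in negative cells, at least 40.1-fold higher (adjusted p = 0.00147). Lsp1 was at 1281 ± 289 RPKM against 45.6 ± 14.0 (log2 5.01, SE 0.38, adjusted p = 6.85e-08). Mndal and Ifi203, interferon-inducible genes of the p200 family, had ratios of 989 (interval 177 to 39120, adjusted p = 5.77e-06) and 319 (interval 56.7 to 12620, adjusted p = 0.000113). Stc1 was at least 155-fold higher (13.1 ± 1.85 RPKM, adjusted p = 0.000737). Gata2 was at 6.09 ± 1.02 RPKM against 43.4 ± 26.4 (log2 -2.86, SE 0.46, adjusted p = 0.00136). Muc13, a transmembrane mucin gene, was lower (log2 -7.19, SE 1.10, adjusted p = 0.000760). Itgam was higher in positive cells (12.3 ± 1.38 RPKM against 1.71 ± 1.24, log2 3.28, SE 0.68, adjusted p = 0.0112, and 0.1003 without negative library 2). Hdc, the histamine-forming enzyme gene of mast cells and basophils, was at 2.06 ± 2.76 RPKM against 58.7 ± 26.8 (log2 -4.76, SE 1.20, adjusted p = 0.0400), and its adjusted p was 0.0627 to 0.212 without any library but positive library 1.

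By list, 7 of 19 early lymphoid genes were called higher at FL E11.5 (11 adjusted over the list alone, adjusted p = 4.98e-17). All 20 erythroid genes lay below 0, 3 called lower (13 adjusted over the list alone, adjusted p = 3.71e-17). In the megakaryocyte list 4 of 16 were called lower (11 adjusted over the list alone, adjusted p = 2.75e-18). The mast cell and basophil list had 1 of 7 called lower (adjusted p = 7.94e-05) and the heme and iron list 1 of 14 (adjusted p = 2.50e-07). The T lineage list had 1 of 9 called higher (adjusted p = 0.00477). With an estimated correlation these adjusted p-values were 0.000312, 0.0163, 5.84e-05, 0.00731, 0.0203 and 0.0413. The T lineage call was lost with no filter (0.0586) and with the replicate block (0.101).

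The B lineage list had 1 of 18 genes called higher at FL E11.5 (adjusted p = 0.00467, and adjusted p = 0.130 with an estimated correlation), and the fetal programme list had 11 of 12 above 0 (adjusted p = 0.00315, and adjusted p = 0.107 with an estimated correlation). The interferon list lay higher (adjusted p = 0.00890, and adjusted p = 0.330 with an estimated correlation), with 0.113 without negative library 2 and 0.111 without negative library 3. The list of MHC class II and presentation genes lay higher (adjusted p = 0.0396, and adjusted p = 0.330 with an estimated correlation), with 0.103, 0.448 and 0.179 without negative library 2, negative library 3 and positive library 1. The embryonic globin list lay lower (adjusted p = 0.0384, and adjusted p = 0.244 with an estimated correlation), with 0.0718, 0.0593 and 0.121 without negative library 1, negative library 2 and positive library 3. The lists of granulocyte-monocyte (0.461), macrophage (0.461), stem cell (0.952), endothelial (0.136), hepatoblast and endoderm (0.706), mesenchyme (0.952), proliferation (0.440), immediate early and stress (0.440) and cytokine receptor genes (0.185) were not called.

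The ribosomal protein list lay lower in positive cells at FL E11.5 (adjusted p = 1.05e-07, and adjusted p = 0.118 with an estimated correlation), with 20 of 76 genes above 0 and 4 called lower. Negative library 1 held 149882 counts and stood apart in these genes, with Rps18 at 16680 RPKM and Rpl35 at 7496. Libraries of the groups overlapped in all 4 called genes, among them Rps18 and Rpl35, and without that library the adjusted p of the list was 0.0157. The count of 229 was 144 and 111 without negative libraries 1 and 2, and 103, 123 and 128 without positive libraries 1, 2 and 3. The limma test planned at first called 442 genes.

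**Figure D1:**
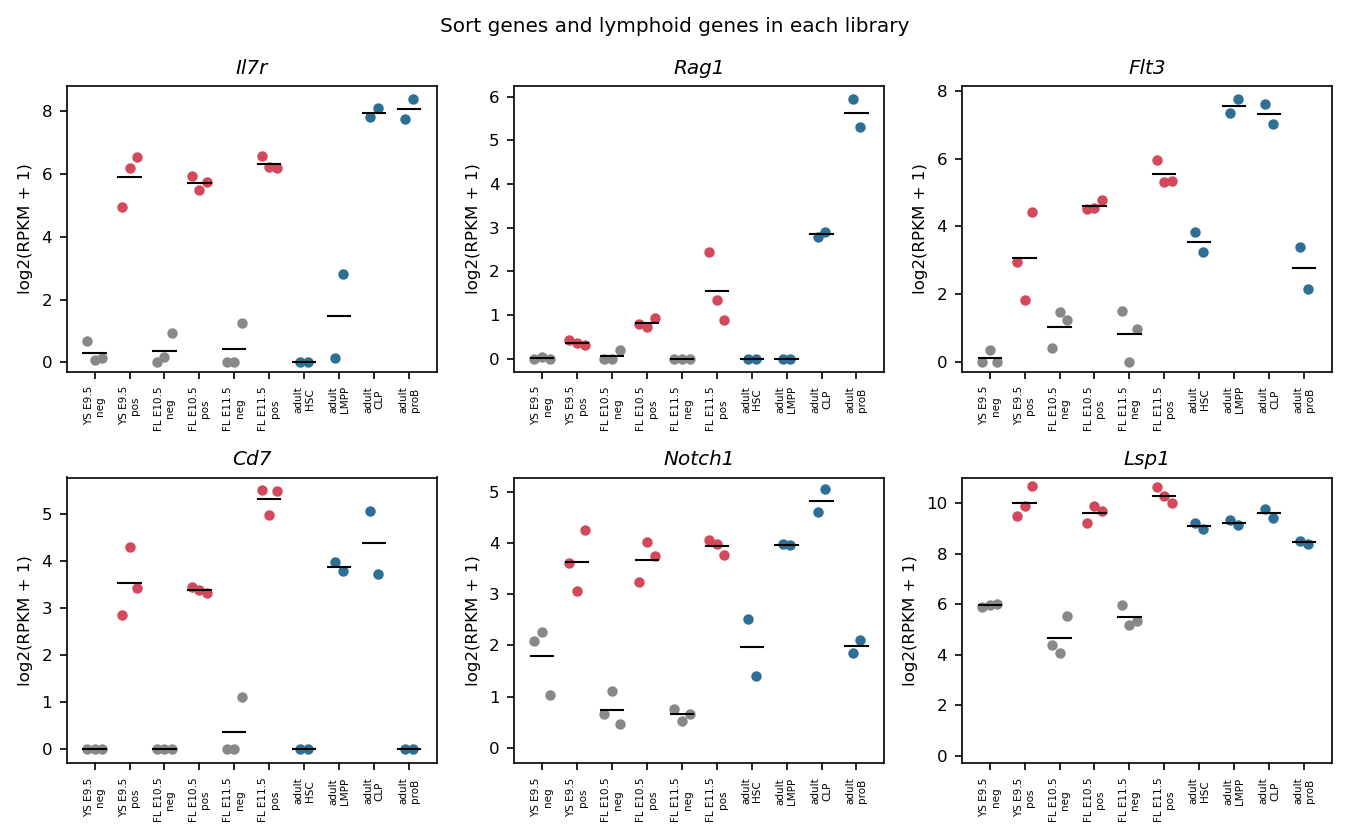
Level of 6 genes in each of the 26 libraries, as log2 of RPKM plus 1 on the vertical axis, by group on the horizontal axis. Dots are libraries (grey, fetal negative; red, fetal positive; blue, adult) and bars are means. Positive libraries lie above negative ones at each stage in all 6 panels.

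The overlap of the 3 fetal comparisons asked whether the positive cells of each stage share transcripts. A common set of 39 genes was called higher in all 3, against 0.00564 expected by chance (71 with DESeq2 and 2 in fits of the compared groups alone). Beside the gate genes it holds the lymphoid and leukocyte genes Cd7, Cd27, Notch1, Ets1, Ptprc, Lsp1, Gimap6, Gimap7, Lax1 and Klrd1, the nuclear receptor gene Rorc, the myeloid surface genes Cd33 and Il1r2, the cell cycle gene Ccnd2, and Mn1, Marcks, Dusp6, Gsn, Stc1 and Cdh17. The others are Gngt2, Dpysl2, Ppp1r16b, Cd47, Mndal, St8sia4, Tnfrsf13c, Gpr171, Tshz3, Gem, Ift57, Napsa, Serpinb1a, Ifitm3, Prss2, P2ry12 and Gpr65. Among lower genes, FL E11.5 shared 2 with the yolk sac and 3 with FL E10.5 (0.0241 expected by chance in each).

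The yolk sac and FL E10.5 comparisons shared 41 higher genes (0.494 expected by chance), the yolk sac and FL E11.5 45 (0.674), and FL E10.5 and FL E11.5 83 (1.26). Across 13136 genes the log2 changes of the yolk sac correlated with those of FL E10.5 at a Pearson r of 0.348 and a Spearman rho of 0.254, and with those of FL E11.5 at 0.360 and 0.268. FL E10.5 and FL E11.5 correlated at 0.476 and 0.450. Genes are not independent replicates. The 39 genes became 24, 25 and 20 without yolk sac negative libraries 1, 2 and 3 and 24 without yolk sac positive library 3. They became 23 and 20 without FL E10.5 negative libraries 1 and 2 and 21 without FL E11.5 negative library 2. Single libraries also moved the pairwise counts, which then ran from 20 to 50, from 22 to 56 and from 30 to 75.

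Positive cells of FL E10.5 were compared with those of YS E9.5 to ask whether the 2 tissues and days differ. Lsp1 was at 789 ± 186 RPKM against 1104 ± 485, Il7r at 52.2 ± 8.06 against 65.2 ± 32.3, Flt3 at 23.6 ± 2.35 against 9.92 ± 9.48 and Rag1 at 0.768 ± 0.139 against 0.286 ± 0.0562. The early lymphoid list was not called (0.156). No gene was called with edgeR, where 863 had an unadjusted p under 0.05. DESeq2 called 18 genes, limma 2, limma after quantile normalization 4, and edgeR with no filter 29 (9 higher and 20 lower). The erythroid list lay higher in the fetal liver cells, with 19 of 20 genes above 0 and none called (7 adjusted over the list alone, adjusted p = 7.08e-15), and the endothelial list lower with 3 of 16 above 0 (adjusted p = 1.14e-05). Both held with an estimated correlation (adjusted p = 0.0443 and 0.0236). The megakaryocyte list lay higher (adjusted p = 0.000720, and adjusted p = 0.0658 with an estimated correlation), as did the immediate early and stress list (adjusted p = 6.44e-05, and adjusted p = 0.0658 with an estimated correlation).

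In that comparison the hepatoblast and endoderm list lay lower in FL E10.5, with 0 of 21 genes above 0 (adjusted p = 2.39e-09, and adjusted p = 0.290 with an estimated correlation), and so did mesenchyme (adjusted p = 0.00376, and adjusted p = 0.441 with an estimated correlation) and fetal programme genes (adjusted p = 0.0188, and adjusted p = 0.270 with an estimated correlation). Apoa1 was at 0.837 RPKM in FL E10.5 and 1962 ± 3397 in YS E9.5 positive cells. Without both yolk sac libraries numbered 1 the adjusted p-values of the 3 lists were 0.325, 0.901 and 0.508. The calls of the MHC class II and presentation list (adjusted p = 0.00376, and adjusted p = 0.270 with an estimated correlation) and of the ribosomal protein list (adjusted p = 0.0306, and adjusted p = 0.462 with an estimated correlation) ended without those 2 libraries as well (0.214 and 0.489), and without FL E10.5 positive library 3 (0.547 and 0.213).

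Positive cells of FL E11.5 were then compared with those of FL E10.5, where the day, the gate and the genotype all change. Genes of the immediate early response, which cells switch on within minutes of stimulation or handling, were lower at FL E11.5. With edgeR 3 genes were called, all lower, beside 405 at an unadjusted p under 0.05. Genes called higher appeared with no filter (4 of 19), with DESeq2 (6 of 35), after quantile normalization (2 of 12) and in a fit of both groups alone (31 of 81). Fos was at 10.3 ± 3.54 RPKM against 189 ± 111 (log2 -4.11, SE 0.61, adjusted p = 0.0130), Zfp36 at 14.5 against 105 (log2 -2.77, adjusted p = 0.0329) and Klf2, a transcription factor of lymphocyte and endothelial quiescence, at 0.617 against 23.6 (log2 -5.16, adjusted p = 0.0378). In the immediate early and stress list 2 of 18 genes were called lower (11 adjusted over the list alone) and 2 lay above 0 (adjusted p = 2.99e-26). The megakaryocyte list had 1 of 16 above 0 (adjusted p = 6.17e-14) and the mast cell and basophil list 0 of 7 (adjusted p = 0.00184). These held with an estimated correlation (adjusted p = 5.51e-05, 0.000225 and 0.0365), the last with 0.0819 without FL E10.5 positive library 3.

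The erythroid list was also lower at FL E11.5 than at FL E10.5 (adjusted p = 1.38e-09, and adjusted p = 0.0953 with an estimated correlation), and the B lineage list lay higher, with 13 of 18 genes above 0 (adjusted p = 0.00100, and adjusted p = 0.0953 with an estimated correlation). The embryonic globin (adjusted p = 0.00631, and adjusted p = 0.134 with an estimated correlation), interferon (adjusted p = 0.0295, and adjusted p = 0.512 with an estimated correlation) and ribosomal protein lists (adjusted p = 0.0202, and adjusted p = 0.541 with an estimated correlation) were called at the preset correlation alone. The first had 0.0842 and 0.0520 without FL E10.5 positive library 3 and FL E11.5 positive library 3, the second 0.1002 to 0.464 without FL E10.5 positive library 1 or 2 or FL E11.5 positive library 1, and the third 0.152 to 0.390 without FL E10.5 positive library 2 or 3 or FL E11.5 positive library 3. Fos ran from 32.83 to 313.6 RPKM in the YS E9.5 and FL E10.5 libraries and from 0 to 14.39 in both gates of FL E11.5. The count of 3 was 1 without FL E10.5 positive library 2 or FL E11.5 positive library 2, and 0 without FL E10.5 positive library 3 or FL E11.5 positive library 1 or 3.

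The difference between the positive and negative cells was compared between stages as an interaction. No gene was called with edgeR between FL E10.5 and YS E9.5 (309 at an unadjusted p under 0.05) or between FL E11.5 and FL E10.5 (242). In the first, DESeq2 and limma called 0 genes as well. In the second DESeq2 called 1, limma 0, limma after quantile normalization 1, and a fit of the 4 groups alone 22 (2 higher and 20 lower). Between FL E10.5 and YS E9.5 the granulocyte-monocyte list lay higher, with 19 of 20 genes above 0 (adjusted p = 3.55e-07, and adjusted p = 0.0369 with an estimated correlation). Between FL E11.5 and FL E10.5 the megakaryocyte list lay lower, with 2 of 16 genes above 0 (adjusted p = 1.26e-15, and adjusted p = 0.000154 with an estimated correlation). Other list calls did not hold with an estimated correlation, whose adjusted p-values were 0.338 to 0.609 in the first and 0.0517 to 0.352 in the second.

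**Figure D2:**
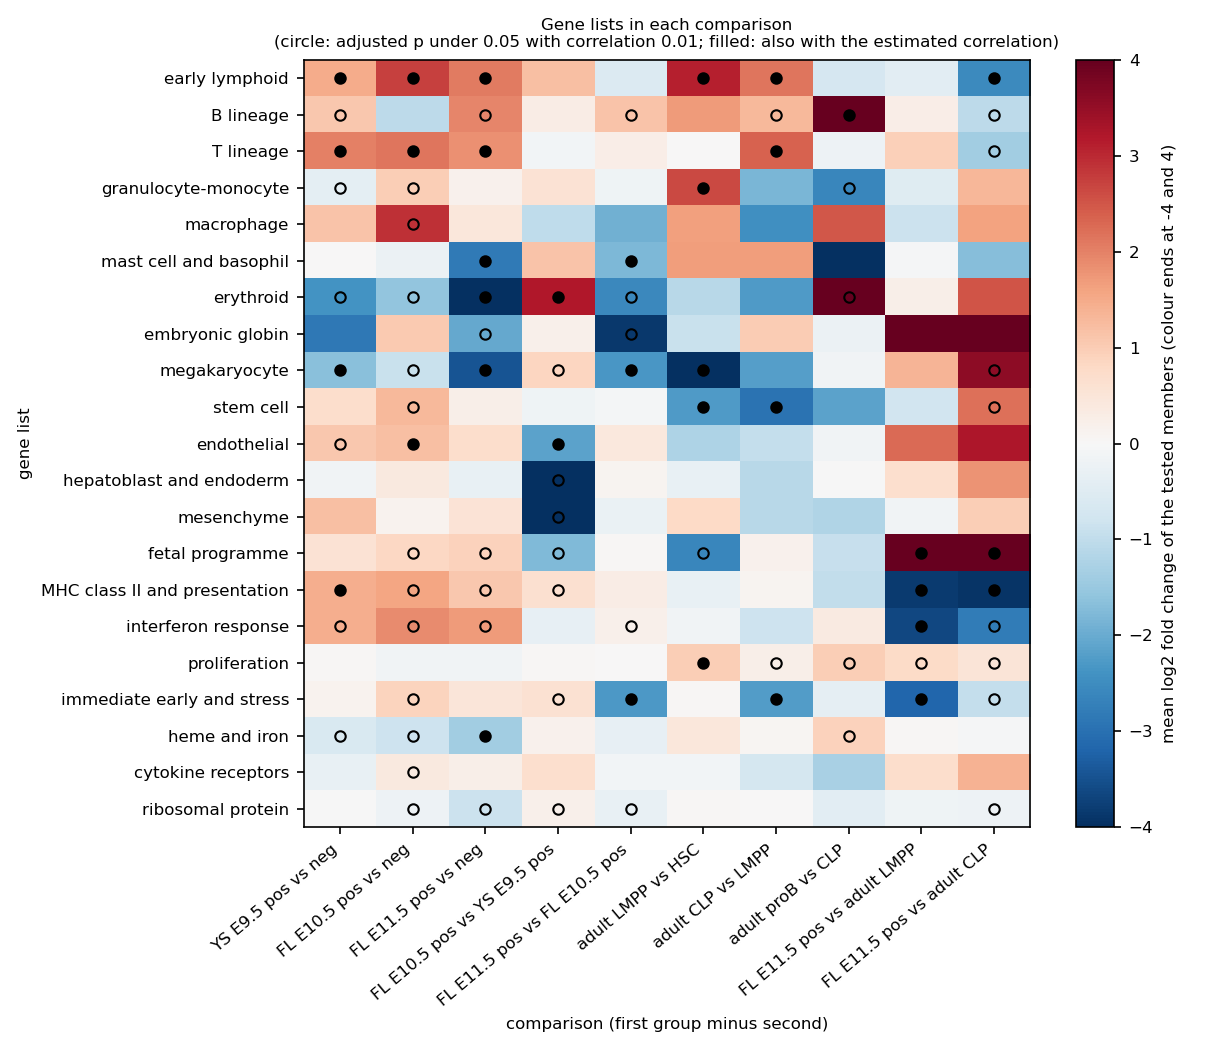
Mean fitted log2 fold change of each of the 21 gene lists (vertical axis) in the 10 comparisons between groups (horizontal axis), as colour. Open circles mark lists with an adjusted p under 0.05 at the preset correlation, filled circles those also under it with the estimated correlation. The early lymphoid list is filled in all 3 comparisons of positive with negative cells.

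The adult LMPP were compared with HSC to trace the first step towards lymphoid cells in bone marrow. LMPP held lymphoid and myeloid transcripts and more of the division genes, and HSC held platelet and stem cell transcripts. Gpr97, an adhesion receptor of leukocytes, was at 137 ± 18.6 RPKM against 3.32 ± 1.24 (log2 5.44, SE 0.50, adjusted p = 2.89e-06). Rag2 was at 10.8 ± 0.815 RPKM and at 0 in HSC, at least 62.9-fold higher (adjusted p = 0.00200). Mpo, myeloperoxidase of granulocyte precursors, was at 379 ± 243 RPKM against 3.17 ± 4.04 (log2 6.97, SE 1.01, adjusted p = 0.000464). Mpl, the thrombopoietin receptor gene, was at 20.9 ± 3.75 RPKM against 268 ± 8.64 (log2 -3.61, SE 0.52, adjusted p = 0.000652), and Esam, an adhesion protein of stem cells and endothelium, at 1.99 ± 0.252 against 84.4 ± 23.8 (log2 -5.33, SE 0.80, adjusted p = 0.000896).

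Between LMPP and HSC 323 genes were called, 204 higher and 119 lower in LMPP, a balance that depended on the test (312 and 421 with limma at a pseudocount of 1, 265 and 265 at 0.1, 347 and 366 after quantile normalization, 33 and 36 in a fit of both groups alone). The gate genes followed the labels, Cd48 at 516 ± 64.9 RPKM against 15.2 ± 3.89 (adjusted p = 0.00110) and Slamf1 at 0 against 35.2 ± 13.1, at least 187-fold lower (adjusted p = 0.0284, and 0.0604 to 0.160 whichever of the 4 libraries was left out). Dntt was at 1057 ± 188 RPKM and at 0 in HSC, at least 3687-fold higher (adjusted p = 0.0348), with an adjusted p of 0.188, 0.140 and 0.0799 without HSC library 2, HSC library 3 and LMPP library 3. Cenpf, a kinetochore protein gene, was at 18.5 ± 12.5 RPKM against 2.71 ± 0.185 (log2 2.84, SE 0.40, adjusted p = 0.000387). In the early lymphoid list 7 of 19 genes were called higher (9 adjusted over the list alone, adjusted p = 1.36e-09), in the granulocyte-monocyte list 4 of 20 (8 adjusted over the list alone, adjusted p = 1.20e-05) and in the proliferation list 5 of 25 (11 adjusted over the list alone, adjusted p = 1.58e-11). In the megakaryocyte list 6 of 16 were called lower (12 adjusted over the list alone, adjusted p = 1.90e-14) and in the stem cell list 3 of 19 (8 adjusted over the list alone, adjusted p = 5.15e-08). With an estimated correlation the 5 adjusted p-values were 0.00208, 0.0337, 0.0206, 0.000289 and 0.00133. The fetal programme list lay lower (adjusted p = 0.0307, and adjusted p = 0.296 with an estimated correlation), with 0.339 without HSC library 3 and 0.291 without LMPP library 3. The count was 170 without HSC library 2 and 155 without LMPP library 3, and the limma test planned at first called 733 genes.

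The step from LMPP to CLP was compared next. CLP held more of the recombinase and early lymphoid transcripts and less of the stem cell transcripts. Rag1 was at 6.22 ± 0.415 RPKM and at 0 in LMPP, at least 89.4-fold higher (adjusted p = 0.00100). Hes1, a target of Notch signalling, was at 38.4 ± 23.1 RPKM against 0.484 ± 0.685 (log2 6.16, SE 1.18, adjusted p = 0.00829, and 0.0556 without LMPP library 3). Ly86, a partner of the receptor RP105 on B and myeloid cells, had a ratio of 3188 (interval 572 to 126000, adjusted p = 0.000380). Gata2 was at 0.377 ± 0.0803 RPKM against 17.99 ± 1.32 (log2 -5.39, SE 0.73, adjusted p = 0.000380). Mpl was at 0 in CLP, at least 86.0-fold lower (adjusted p = 4.26e-05).

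Of the genes tested, 214 were called between CLP and LMPP, 50 higher and 164 lower in CLP (169 and 190 after quantile normalization, 16 and 18 in a fit of both groups alone). Of the gate genes, Kit was at 17.1 ± 4.33 RPKM against 94.2 ± 8.82 (adjusted p = 0.00266) and Il7r at 250 ± 38.3 against 3.05 ± 4.19 (adjusted p = 0.00623). In the early lymphoid list 3 of 19 were called higher and 17 lay above 0 (adjusted p = 4.09e-09), and in the T lineage list 1 of 9 was called higher (adjusted p = 0.00743). In the stem cell list 6 of 19 were called lower (adjusted p = 8.41e-08), and in the immediate early and stress list 1 of 18 was called lower and none lay above 0 (adjusted p = 2.15e-05). With an estimated correlation the 4 adjusted p-values were 0.00332, 0.0413, 0.000765 and 0.0413. The granulocyte-monocyte and megakaryocyte lists were not called (0.0926 and 0.0992). The T lineage call had 0.159 with no filter and 0.0519 without LMPP library 2. The B lineage (adjusted p = 0.0305, and adjusted p = 0.369 with an estimated correlation) and proliferation lists (adjusted p = 0.0385, and adjusted p = 0.557 with an estimated correlation) were called at the preset correlation alone, and both calls ended without CLP library 3 (0.211 and 0.176) and without LMPP library 2 (0.212 and 0.866). The limma test planned at first called 450 genes.

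The last adult step, from CLP to pro-B cells, had the most called genes of the adult steps. Pro-B cells held the transcripts of the pre-B cell receptor and of B lineage identity, and less Mpo, Flt3 and Cd34. Igll1, a surrogate light chain gene, was at 9781 ± 447 RPKM with a ratio of 42280 (interval 7589 to 1670000, adjusted p = 0.000114). Vpreb3 was at 6260 ± 16.9 RPKM against 5.30 ± 7.501 (log2 11.24, SE 2.15, adjusted p = 0.00319). The gate gene Cd19 was at 286 ± 13.4 RPKM and at 0 in CLP, at least 1168-fold higher (adjusted p = 0.00172), and Lef1, a transcription factor of early B and T cells, at least 458-fold higher (110 ± 21.2 RPKM, adjusted p = 0.000161). Mpo was at 0.242 RPKM against 398 ± 188 (log2 -10.39, SE 1.23, adjusted p = 7.98e-06). Flt3 was at 6.53 ± 4.35 RPKM against 164 ± 48.6 (log2 -4.48, SE 0.94, adjusted p = 0.00303), and Cd34, a surface protein of progenitors, had a ratio of 6584 in favour of CLP (interval 1181 to 260100, adjusted p = 1.07e-10).

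Between pro-B cells and CLP 1718 genes were called, 668 higher and 1050 lower (106 and 62 in a fit of both groups alone). In the B lineage list 12 of 18 were called higher (14 adjusted over the list alone, adjusted p = 4.03e-10, and 0.00660 with an estimated correlation). The proliferation list had 10 of 25 called higher and 1 lower (adjusted p = 2.63e-07, and adjusted p = 0.1245 with an estimated correlation), Rrm2, a subunit of ribonucleotide reductase, at 1065 ± 178 RPKM against 183 ± 34.1 (log2 2.75, SE 0.39, adjusted p = 6.61e-05). The granulocyte-monocyte list had 9 of 20 called lower and 1 higher (adjusted p = 4.57e-05, and adjusted p = 0.106 with an estimated correlation). In the early lymphoid and stem cell lists 5 genes each were called lower, and neither list was called (0.0636 each). The erythroid list had 6 of 20 called higher (adjusted p = 0.00393, and adjusted p = 0.543 with an estimated correlation), with 0.571 without pro-B library 2 and 0.0730 without CLP library 2. Gata1 was at 44.15 RPKM in pro-B library 2 and 0.1391 in pro-B library 3, and Gypa, a red cell surface protein gene, at 246.8 and 0.139. The heme and iron list (adjusted p = 0.0497, and adjusted p = 0.464 with an estimated correlation) had 0.593 without pro-B library 2 and 0.128 without CLP library 2.

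The adult steps were then followed into the fetal cells. Of the 39 genes shared by the positive fetal cells, 8 were called higher in LMPP than in HSC (0.606 expected by chance), Cd33, Cd7, Flt3, Gimap7, Gpr171, Il1r2, Notch1 and Serpinb1a, and Rorc was called lower. Il7r and Klrd1 were called higher in CLP than in LMPP (0.148 expected). Il7r was sorted on at all 3 fetal stages and Flt3 at FL E11.5. Their place among the shared genes was set in part by these gates, which the values expected by chance do not allow for. In pro-B cells 16 of the 39 were called lower than in CLP (3.12 expected) and 6 higher (1.98). The signature of 100 genes higher in LMPP than in HSC lay higher in the positive cells at all 3 stages. Of its genes 5 were called higher in the yolk sac, 13 at FL E10.5 and 21 at FL E11.5, and none lower (adjusted p = 2.32e-07, 1.07e-14 and 4.69e-17). With an estimated correlation these were 0.00421, 0.000152 and 0.000152. Its mean log2 changes of 0.77, 1.22 and 1.59 were 0.36, 0.64 and 0.79 when it was chosen without HSC library 2, and 0.43, 0.64 and 0.95 with 200 genes.

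The signature of 48 genes higher in CLP than in LMPP also lay higher in the mean. Only 26, 31 and 31 of its genes lay above 0. Its mean at FL E10.5 was 1.05, and 1.16 without positive library 3 (adjusted p = 6.46e-07). Its median log2 changes were 0.16, 0.52 and 0.34. It had 3, 3 and 9 genes called higher (adjusted p = 2.49e-05, 3.00e-07 and 1.14e-05, and 0.000152, 7.99e-05 and 0.000152 with an estimated correlation). Chosen without LMPP library 2, it gave 0.186, 0.106 and 0.0694. The signature of 100 genes higher in pro-B cells than in CLP was not called at any stage (adjusted p = 0.558, 0.341 and 0.296). Chosen without pro-B library 3 it lay lower at FL E10.5 (-0.58, adjusted p = 0.00423) and FL E11.5 (-0.59, adjusted p = 0.00967), as means of log2 changes. That choice rests on pro-B library 2, which held red cell transcripts, and the signature of 100 genes includes the erythroid genes Car1, Gypa and Ermap, so that these values do not speak of B lineage genes alone.

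All 18 fetal libraries, negative ones included, correlated most with the mean of the LMPP among the adult groups. Over the 1000 most variable genes the positive cells of FL E11.5 correlated at 0.618 ± 0.0109 with LMPP and 0.596 ± 0.0270 with CLP, those of FL E10.5 at 0.596 and 0.541, and those of YS E9.5 at 0.527 and 0.460. With CLP, FL E10.5 positive libraries 1, 2 and 3 stood at 0.4995, 0.523 and 0.5989, the last being the library with Dntt. The negative cells of FL E11.5 correlated at 0.508 with LMPP, 0.441 with HSC and 0.365 with CLP. Over these genes 17 libraries were closest to LMPP and FL E11.5 positive library 1 to CLP. With a single library for LMPP the number closest to it was 1 without LMPP library 2 and 8 without LMPP library 3.

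**Figure D3:**
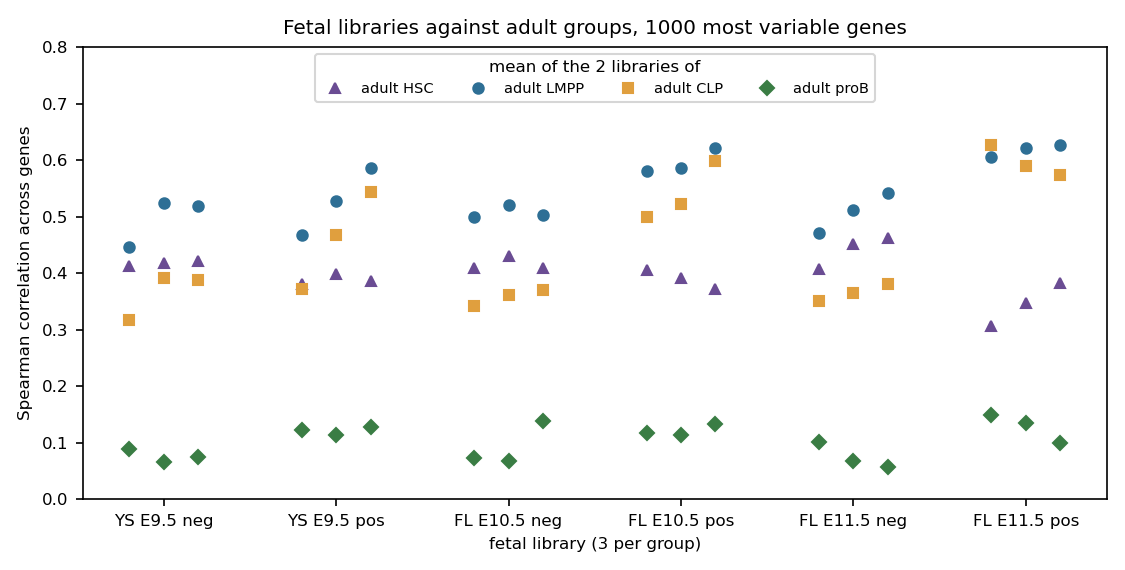
Spearman correlation (vertical axis) of each of the 18 fetal libraries (horizontal axis, 3 per group) with the mean of the 2 libraries of each adult group, across the 1000 most variable genes. Symbols are the adult groups. The correlation with CLP is 0.596 in FL E11.5 positive and 0.365 in FL E11.5 negative cells as group means.

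Positive cells of FL E11.5 were set against adult LMPP to find what separates fetal from adult lymphoid-primed cells. Stage goes with tissue, gate and sex here, since Xist was at 11.31 to 41.93 RPKM in the adult libraries and at 0.6806 to 4.964 in the fetal ones, and Ddx3y, on the Y chromosome, at 0 to 0.3664 against 8.624 to 38.52. The fetal cells held the fetal RNA-binding programme and less of the antigen presentation and interferon transcripts. Lin28b, a repressor of let-7 maturation, was at 32.04 ± 9.98 RPKM and at 0 in LMPP, at least 407-fold higher (adjusted p = 1.47e-05). Igf2bp1, which binds messenger RNA in fetal cells, had a ratio of 1164 (interval 209 to 46000, adjusted p = 7.88e-07). Dntt was at 0 in all 3 fetal libraries and at 1057 ± 188 RPKM in LMPP, at least 5842-fold lower (adjusted p = 0.00570). H2-K1, an MHC class I gene, was at 28.5 ± 6.64 RPKM against 485 ± 2.62 (log2 -4.03, SE 0.38, adjusted p = 3.33e-06).

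Between FL E11.5 positive cells and LMPP 823 genes were called, 432 higher and 391 lower. That balance turned with the DESeq2 size factors (394 and 463), limma at a pseudocount of 1 (502 and 683), quantile normalization (569 and 674) and a fit of both groups alone (755 and 878). All 12 fetal programme genes lay above 0, 9 called higher (adjusted p = 6.16e-20). All 12 genes of MHC class II and presentation lay below 0, 8 called lower (adjusted p = 3.53e-16), as did all 20 interferon genes, 9 called lower (adjusted p = 3.95e-10). The immediate early and stress list had 10 of 18 called lower (adjusted p = 1.74e-12), with Fos at 10.3 ± 3.54 RPKM against 1166 ± 164 (log2 -6.77, SE 0.70, adjusted p = 8.04e-06). With an estimated correlation the 4 adjusted p-values were 0.000112, 0.00110, 0.0401 and 0.00126. The proliferation list had 6 of 25 called higher (adjusted p = 2.20e-05, and adjusted p = 0.164 with an estimated correlation), with 0.153 without LMPP library 2. The early lymphoid list, 3 genes higher and 2 lower, was not called (0.896). Cdh17, a cadherin gene, was at 68.6 ± 6.27 RPKM and at 0 in LMPP, at least 532-fold higher (adjusted p = 1.47e-05). Sell, which homes lymphocytes to lymph nodes, was at 6.53 ± 4.02 RPKM against 147 ± 13.0 (log2 -4.46, SE 0.98, adjusted p = 0.00778). The count of 823 was 491 and 378 without LMPP libraries 2 and 3, and 547, 425 and 431 without FL E11.5 positive libraries 1, 2 and 3.

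Against adult CLP the FL E11.5 positive cells had the fetal programme and less of the early lymphoid and antigen presentation transcripts. Dntt was at 0 against 5884 ± 710 RPKM, at least 36310-fold lower (adjusted p = 0.00193). Ly6d, a marker of B-biased progenitors, had a ratio of 1021 in favour of CLP (interval 183 to 40410). Mpl was at 31.3 ± 10 RPKM and at 0 in CLP, at least 145-fold higher (adjusted p = 4.00e-06), and Gata2 at 6.09 ± 1.02 against 0.377 ± 0.0803 (log2 3.88, SE 0.70, adjusted p = 0.00142). Il7r and Rag1 were lower by fitted value but not called (log2 -1.61 and -1.44, adjusted p = 0.258 and 0.231).

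Between FL E11.5 positive cells and CLP 1114 genes were called, 708 higher and 406 lower (784 and 724 after quantile normalization, 720 and 639 in a fit of both groups alone, 618 and 479 with the DESeq2 size factors). In the fetal programme list 9 of 12 were called higher (adjusted p = 2.96e-14), in the MHC class II and presentation list 10 of 12 were called lower (adjusted p = 1.16e-17), and in the early lymphoid list 5 of 19 were called lower (9 adjusted over the list alone, adjusted p = 8.40e-06). With an estimated correlation these were 0.000651, 0.000651 and 0.0204. The interferon list had 8 of 20 called lower (adjusted p = 6.08e-07, and adjusted p = 0.0762 with an estimated correlation), and the immediate early and stress list 5 of 18 lower and 2 higher (adjusted p = 0.000271, and adjusted p = 0.0753 with an estimated correlation). The stem cell list had 6 of 19 called higher (adjusted p = 0.00853, and adjusted p = 0.0600 with an estimated correlation), with 0.0941 without CLP library 3, and the megakaryocyte list 4 of 16 (adjusted p = 0.00508, and adjusted p = 0.0762 with an estimated correlation), with 0.0582 without CLP library 2. The T lineage list (adjusted p = 0.0240, and adjusted p = 0.0762 with an estimated correlation) had 0.0825 without CLP library 3 and 0.108 with no filter. The B lineage list (adjusted p = 0.0175, and adjusted p = 0.201 with an estimated correlation) had 0.130 without CLP library 3 and 0.0672 without FL E11.5 positive library 3. The proliferation list (adjusted p = 0.0240, and adjusted p = 0.395 with an estimated correlation) and the ribosomal protein list (adjusted p = 0.00753, and adjusted p = 0.395 with an estimated correlation) had 0.1254 and 0.103 without CLP library 2. The count of 1114 was 699 without CLP library 2, and 620 and 607 without FL E11.5 positive libraries 2 and 3.

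**Figure D4:**
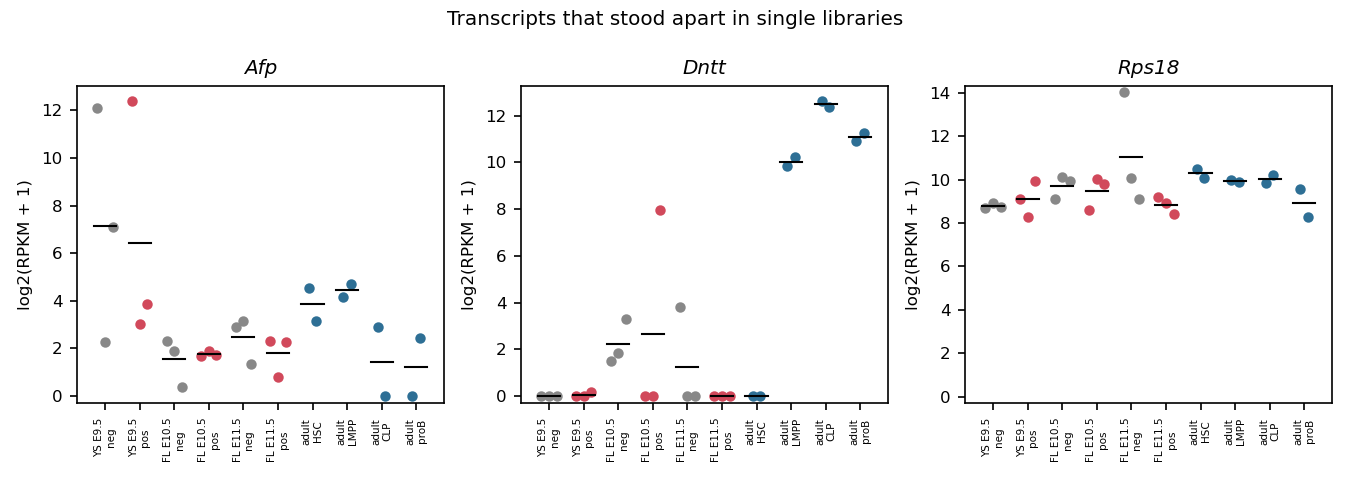
Level of Afp, Dntt and Rps18 in each of the 26 libraries, as log2 of RPKM plus 1 on the vertical axis, by group on the horizontal axis, with bars at the means. Afp stands high in both yolk sac libraries numbered 1, Dntt in FL E10.5 positive library 3 and in adult LMPP, CLP and pro-B cells, and Rps18 in FL E11.5 negative library 1.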

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

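All tests of the yolk sac endoderm transcripts and of the adult transcripts in a fetal liver library, and the test of low depth for the ribosomal protein genes, were chosen only after the result was seen, whereas the pseudogene and gene length tests were written before theirs.

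A test of the difference between stages singled out 2 lists. In the comparison of positive with negative cells the granulocyte-monocyte list differed by a mean log2 of 1.397 more at FL E10.5 than at YS E9.5 (adjusted p = 0.0369 with an estimated correlation, and 0.0541 with fry), where both tissue and day change. The megakaryocyte list differed by a mean log2 of -2.587 between FL E11.5 and FL E10.5 (adjusted p = 0.000154 with an estimated correlation), where day, gate and genotype change together. Both means include fitted values of genes near 0, which depend on the prior count and are no bound.

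Endoderm transcripts stood high in both yolk sac libraries numbered 1, at 4319 and 5404 RPKM for Afp, 5483 and 5884 for Apoa1, 7132 and 5620 for Apoa2 and 4280 and 3095 for Ttr. Greater depth of the pair is excluded, since the other 4 yolk sac libraries together would then hold a median of 12865 counts per gene and held 58. The other 4 stood at 0.395% of the level of the pair, so progenitors of that day did not express these transcripts at that level in general. This low level is part of the pattern itself, so expression by the cells of the pair alone is not excluded. RNA from endoderm cells in that pair is a candidate source, with 100% of the 21 listed genes higher in both libraries than in each other fetal library, although the sort for lineage-negative Kit+ cells should remove such cells. The ratio between the 2 libraries varied little from gene to gene (SD of its log2 0.564 over 19 genes at 10 RPKM or more in both). The excess was not of endoderm genes alone. In FL E10.5 against YS E9.5 positive cells the mean log2 of the mesenchyme list was -5.902, and -0.2078 without YS E9.5 positive library 1.

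Dntt stood at 250.6 RPKM in FL E10.5 positive library 3, which is 4.259% of the adult CLP level, and at 0 in the other positive libraries of that group. RNA from adult LMPP is excluded, since 12.5% of their abundant genes absent from both sister libraries reached 50% of the level that Dntt predicts (Ly6a stood at 18.2 RPKM against 113.1). RNA from adult pro-B cells is excluded too, with 7.407% of such genes (Igll1 at 0.327 RPKM against 1115, Vpreb3 at 0.955 against 714). RNA from adult CLP is a candidate source, with 100% of the 10 such genes at 50% or more of that level, among them Ifi27l2a (43.87 RPKM against 24.29) and Blnk (19.06 against 13.47), although the label gives fetal liver as the tissue sorted. The design names no fetal group of that kind, so that a biological source within the embryo was not tested and stays open.

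Ribosomal protein genes stood high in FL E11.5 negative library 1, with a median log2 ratio to the group's other libraries of 0.827 against -0.27 for other genes. Counting error at its low depth does not account for all of this. Of the 76 genes, 38.16% lay above all other 25 libraries by more than the counting interval allows. That interval takes reads as independent molecules, which amplified reads are not, so low depth as such is not excluded. Reads shared with pseudogenes may contribute, since other genes with an annotated pseudogene stood 0.678 higher on the log2 scale than those without (SE 0.148, 113 of 5010 genes). Length bias may contribute too, as the shortest 20% of other genes stood 1.033 above the longest 20% (SE 0.0544). This length, implied by count and RPKM, had a median in ribosomal protein genes of 8.15% of that in those 5010. The tests do not part pseudogenes from length, as 76.32% of the 76 genes have an annotated pseudogene. No biological explanation was tested.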

How the results depend on the processing

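The tests with DESeq2, with the DESeq2 size factors within edgeR and without both yolk sac libraries numbered 1 were chosen only after the data were seen, as were no filter for the lists and signatures, leaving out libraries for the lists and the similarity, and, for shared genes, all settings but limma at 0.1, quantile normalization and a minimum log2 of 1. limma at a pseudocount of 1, the test planned at first, became an alternative then. The cause of each change below was not tested, except that fits with fewer libraries have fewer degrees of freedom.

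Of 454 calls of named genes, 448 held with the DESeq2 size factors, 449 with the filter at 5 RPKM (1 lost, the rest not tested), 445 with no filter, 410 with the replicate block, 430 with DESeq2 (12 lost, the rest without an adjusted p), 419 with limma at a pseudocount of 1, 404 at 0.1, 406 after quantile normalization and 325 in the fit of the compared groups alone. In every edgeR setting 1 of 47 held in the yolk sac, 19 of 56 at FL E10.5, 27 of 75 at FL E11.5, 9 of 41 for LMPP against HSC, 6 of 34 for CLP against LMPP, 24 of 64 for pro-B cells against CLP, 34 of 64 for FL E11.5 against LMPP and 36 of 70 against CLP. For FL E11.5 against FL E10.5 positive cells 0 of 3 held in every edgeR setting. Of 101 list calls, 37 held with an estimated correlation, 99 with the DESeq2 size factors, 93 with the filter at 5 RPKM, 93 with no filter and 91 with the replicate block. Leaving out single libraries was counted over each pair of a call and a library left out. Calls of named genes held in 1522 such pairs, were lost in 788 and reversed in 2. List calls held in 533 pairs, were lost in 104 and reversed by the direction of the test in 3. With the DESeq2 size factors and the filter at 5 RPKM every count of genes in a comparison stayed within 1.5 times. Signature sizes of 50 and 200 genes could not move the CLP signature, which has 48 genes. Libraries of 149882 and 977021 counts limit what can be seen in FL E11.5 negative cells and CLP, and groups of 2 and 3 limit the calls of genes near 0.

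DESeq2 called 156 genes in the yolk sac, 281 at FL E10.5, 536 at FL E11.5, 18 for FL E10.5 against YS E9.5 positive cells, 35 for FL E11.5 against FL E10.5, 782 for LMPP against HSC, 680 for CLP against LMPP, 1450 for FL E11.5 against LMPP, 1760 against CLP and 1 in the interaction of FL E11.5 and FL E10.5. It shared 79, 86 and 169 higher genes between pairs of stages and 71 between all 3. On simulated data its calls held more false ones than those of edgeR. Those data were drawn from the dispersions of edgeR, so they do not rank the tools on the real data. The fit of the compared groups alone called 2, 368, 867 and 81 genes in the yolk sac, at FL E10.5, at FL E11.5 and for FL E11.5 against FL E10.5. It called 69, 34 and 168 for the 3 adult steps, 1633 for FL E11.5 against LMPP and 22 in the interaction of FL E11.5 and FL E10.5, with 2, 2 and 218 higher genes shared by pairs of stages and 2 by all 3.

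limma at a pseudocount of 1 called 442 genes at FL E11.5, 2 for FL E10.5 against YS E9.5, 8 for FL E11.5 against FL E10.5, 733 for LMPP against HSC and 450 for CLP against LMPP. At 0.1 it called 413, 530 and 399 at FL E11.5, for LMPP against HSC and for CLP against LMPP. After quantile normalization it called 416 at FL E11.5, 4 for FL E10.5 against YS E9.5, 12 for FL E11.5 against FL E10.5, 713 and 359 for those adult steps, 1243 for FL E11.5 against LMPP and 1 in the interaction of FL E11.5 and FL E10.5. No filter gave 29 genes for FL E10.5 against YS E9.5 and 19 for FL E11.5 against FL E10.5.

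With the replicate block 88 genes were called in the yolk sac (55 of the 63), 155 at FL E10.5, 287 at FL E11.5 and 6 for FL E11.5 against FL E10.5. The block lowered the mean log2 of the pro-B signature at FL E11.5 to -0.53 (adjusted p = 0.0464) and ended the T lineage list call there (adjusted p = 0.101). Same-number correlations were 0.373, 0.167 and 0.0877 at FL E10.5 and 0.0443, -0.0248 and 0.0653 at FL E11.5. Adult steps gave 0.0135, -0.00746 and 0.00612. FL E10.5 positive library 1 had -0.2908 and -0.1165 with negatives 2 and 3, so number 1 may pair there. Positive library 3 correlated best with negative library 2 at FL E10.5 (0.162) and in the yolk sac (0.413).

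Leaving out single libraries gave 27 genes (without negative 3) to 90 (positive 1) in the yolk sac, 33 (negative 2) to 70 (positive 3) at FL E10.5, 103 (positive 1) to 171 (negative 3) at FL E11.5 and 0 (positive 1 or 3 of FL E11.5, or 3 of FL E10.5) to 2 (positive 1 of FL E10.5) for FL E11.5 against FL E10.5. It gave 155 (LMPP 3) to 347 (HSC 3) for LMPP against HSC, 378 (LMPP 3) to 547 (FL E11.5 positive 1) for FL E11.5 against LMPP and 607 (FL E11.5 positive 3) to 779 (FL E11.5 positive 1) against CLP. The steps from LMPP to CLP (163 to 299) and from CLP to pro-B cells (1214 to 1959) stayed within 1.5 times. Shared higher genes ran from 20 to 50 (yolk sac and FL E10.5), 22 to 56 (yolk sac and FL E11.5), 30 to 75 (FL E10.5 and FL E11.5) and 20 to 47 (all 3), with the lowest without FL E10.5 negative 2 or yolk sac negative 3 and the highest without yolk sac positive 1 or, for FL E10.5 and FL E11.5, without FL E11.5 negative 1 or positive 3. The LMPP signature ran from 0.36 to 0.87, 0.64 to 1.32 and 0.79 to 1.78 at the 3 stages, lowest without HSC 2. The CLP signature ran from 0.16 to 1.06, 0.32 to 1.44 and 0.35 to 1.85 at the 3 stages, lowest without LMPP 2, and the pro-B signature from -0.82 (without positive 1) to 0.68 (without negative 1) in the yolk sac, -0.58 to 0.53 at FL E10.5 and -0.59 to 0.33 at FL E11.5. From 1 (without LMPP 2) to 18 fetal libraries were closest to LMPP. Without both yolk sac libraries numbered 1, 60 genes were called in the yolk sac (46 shared).

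By the direction of the test, which sets a list against all other genes, 3 lists reversed, and so did 3 genes. The mesenchyme list in FL E10.5 against YS E9.5 positive cells had a mean of -0.21 without YS E9.5 positive library 1, with the test's direction reversed, and down to -6.38 without another library. The proliferation list in CLP against LMPP had -0.0157 without LMPP library 2 (0.79 without LMPP library 3), and the ribosomal protein list in the interaction of FL E11.5 and FL E10.5 had -0.0883 without FL E11.5 negative library 1 (-0.84 without negative library 3), again by the test's direction. Apoa1 in the yolk sac had -11.73 without positive library 1 (5.59 without negative library 1), Igf2bp3 in pro-B cells against CLP 4.10 without CLP library 2 (-5.59 without pro-B library 2), and Ccr2 there 2.37 without CLP library 3 (-9.31 without pro-B library 2). The mean changed sign, with the call lost, in further lists. In FL E10.5 against YS E9.5 these were the fetal programme (0.0591 without YS E9.5 positive library 1) and MHC class II and presentation (-0.12 without FL E10.5 positive library 3). In FL E11.5 against FL E10.5 it was interferon response (-0.0895 without FL E10.5 positive library 2 and -0.43 without FL E11.5 positive library 1), and in pro-B cells against CLP heme and iron (-0.35 without pro-B library 2). In FL E11.5 against CLP these were B lineage (0.18 without CLP library 3) and ribosomal protein (0.25 without CLP library 2). The ribosomal protein list of the interaction of FL E10.5 and YS E9.5 had 0.038 with limma at 0.1, and the fetal programme 0.0713 without both yolk sac libraries numbered 1.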

Other observations

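The gene families below were looked at only after the results were seen, whereas the regrouping of libraries was planned, and no test of an explanation was run on them.

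The GTPases of the Gimap family, which act in lymphocyte survival, leaned towards the positive cells at every stage. Of 8 genes tested, 2 were called higher in the yolk sac, 2 at FL E10.5 and 4 at FL E11.5, none was called lower, and 7, 8 and 8 lay above 0. With the DESeq2 size factors these counts were equal, and after quantile normalization 2, 2 and 5 were called higher and Gimap3 changed direction in the yolk sac. Of 6 genes of the interferon-inducible p200 family, 1, 2 and 2 were called higher, and 4, 5 and 6 lay above 0 (after quantile normalization 1, 1 and 3 called, with Ifi205 changing direction at FL E10.5). The Hoxa genes, which are active in early blood progenitors, had 1 of 8 called, at FL E10.5, with 4, 7 and 8 above 0 at the 3 stages, and after quantile normalization 8, 7 and 7, where 4 were called higher at FL E11.5. Of 4 Hoxb genes none was called at any stage, with 3, 4 and 2 above 0, and 3, 4 and 0 after quantile normalization. In pro-B cells against CLP 4 Hoxa genes were called lower with each scaling, and all 8 lay below 0 except Hoxa6 after quantile normalization. The shift of the median over all genes stayed under 0.1 in every comparison and scaling.

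Sets of libraries were also regrouped. Splits of 3 libraries against 3 are 10 in number, too few for a share under 0.05. The real yolk sac split called 63 genes and the highest other split 240, and 5 of 10 splits called as many as the real one. The 4 others put both libraries numbered 1 on the same side (98, 106, 85 and 240 genes), a structure of the samples, and the remaining splits called 0. Among the splits that part the libraries of each number, only the real one called any gene. At FL E10.5 the real split called 114 genes and the highest other 0 (1 of 10 splits as many). At FL E11.5 these were 229 and 0 (1 of 10), and for FL E11.5 against FL E10.5 positive cells 3 and 0 (1 of 10). Where edgeR called 0 genes every split must call as many, so the splits for FL E10.5 against YS E9.5 positive cells (10 of 10, highest other 0) and the exchanges of libraries for each interaction (40 of 40, highest other 0) say nothing about chance.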
